A study of Saccharomyces cerevisiae with 12 samples.

How the data were processed

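RNA from 12 samples of the Saccharomyces cerevisiae strain L40 was measured on single-colour Agilent expression arrays. The labels give 3 groups of 4 arrays: yeast stably expressing the single-chain antibody fragment scFv-58F, directed against histone H3 acetylated at lysine K9, yeast stably expressing scFv-112A, directed against acetylated HIV-1 integrase and named as the control, and wild type without an intrabody. An intrabody is an antibody fragment made inside the cell. Per the labels' protocols, the intrabody strains were kept on medium without leucine and the wild type on rich YPD medium, while the last overnight culture of every group was in YPD. RNA was extracted with Trizol and checked for integrity, and Cy3-labelled copies were made from the polyadenylated RNA, per the labels' protocols. The labels do not say whether the 4 replicates of a group came from separate cultures.

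Each array file holds the output of Agilent Feature Extraction 10.7.3.1. Its processed signal is, per the file headers, a Cy3 intensity with the local background subtracted and the spatial trend removed within the array, and it is not scaled between arrays. The same files hold the median pixel intensity of each spot and of its background, without further treatment, per the file headers. The authors also deposited a table of log2 values for 5297 probes. On each array these values follow the log2 processed signal with an offset that puts the 75th percentile at 12.8; the offset varied between probes with an SD of 0.0135 to 0.0669 on an array. Each array carries 13048 spots, of which 12512 belong to 6256 gene probes in 2 spots each. These probes stand for 6224 genes, 30 of them with several probes. Names were matched to the annotation of assembly R64: 5750 genes matched and 474 did not and carry the names in the files. The files name another build, so no coordinates are given.

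All 12 arrays could be assigned to a group. The 4 arrays of each group share 1 slide and 1 scan, giving 3 slides and 3 scans, and the replicate number is the position on the slide. Slide and group therefore cannot be told apart. The share of gene spots well above background, as Feature Extraction calls it, was 87.0% to 94.7% per array, 0 spots were saturated, and 25 to 125 spots per array were left out as outliers of the image analysis. The number of arrays limits the precision of every value.

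The log2 of the processed signal was taken, each array's 75th percentile was subtracted, and the 2 spots of a probe were averaged. A gene with several probes was represented by the probe with the highest mean signal over all 12 arrays. Of 29 genes with more than 1 probe above background, 4 called comparisons have probes that differ in sign. A gene was tested when its probe was well above background on at least 4 of the 12 arrays, which left 5827 genes. Group means were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 2-sided), and p was adjusted with the Benjamini-Hochberg method over all genes within a comparison. A gene was called at an adjusted p under 0.05, and the calls of at least 2-fold were counted separately. Fold changes are log2 differences with the SE of the fit, levels are means with the SD of 4 arrays, and n = 4 arrays per group throughout. The 3 comparisons are 58F with 112A, 58F with wild type and 112A with wild type. A gene was set apart in 58F when it was called in the same direction against both other groups. Where a gene was above background on 0 arrays of a group, its fold is a lower bound, computed against the lowest signal called above background. Where it was above background on part of a group's arrays, their number is given. Genes of near-identical families share signal between copies, and their values are uncertain for that reason.

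Gene lists were fixed before the data were examined, as were the comparisons, the tests, the alternative settings and the rule for named genes. There were 38 lists with at least 5 members tested. Each was compared with all other genes by limma's camera with its preset correlation of 0.01 and again with a correlation estimated from the data, with Benjamini-Hochberg adjustment over the 38 lists; 20 genes lacking a value on some array were left out of camera only. A list was called moved at an adjusted p under 0.05. Of all genes, 32.2% were called for 58F with 112A, 61.7% for 58F with wild type and 48.3% for 112A with wild type. Counts of called list members are to be read beside these shares. The subtelomeric list took the 10 highest-numbered reading frames of each chromosome arm, since no usable coordinates were at hand. List names SUS1, MEL1 and HSP150 have no probe. Named genes are, per comparison, the 10 largest rises and falls among called genes whose arrays do not overlap, up to 4 called members of each list with the largest changes, a fixed set of marker and chromatin genes, and the 10 genes set apart in 58F in each direction. The text names part of these. Genes outside this rule are said to have been chosen after their values were seen.

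The calculation was tested on simulated arrays of the 5827 genes, with 50 genes changed at each of 4 sizes in every comparison. At simulated log2 changes of 0.25, 0.5, 1 and 2, 50%, 78%, 96% and 100% were recovered for 58F with 112A. The shares were 46%, 84%, 98% and 100% for 58F with wild type, and 34%, 92%, 96% and 100% for 112A with wild type. False calls made up 6.91%, 9.95% and 5.76% of the calls. The shifted list was recovered each time with 0 other lists called. Genes were drawn independently of each other, so this does not test list calls where genes are correlated.

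The alternatives were scaling by the median, by quantiles or by 7 spike-in sequences, normexp background correction with an offset of 50, the authors' deposited log2 values, no filter and a filter on all 12 arrays, the mean of all probes, another variance model, fits of the 2 groups alone, a replicate block, an estimated correlation for the lists, and leaving out each array. Normexp was applied to the median pixel intensity because the files hold no mean pixel intensity. Cyclic loess scaling, and the counts per list without wild type replicate 1, were added after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.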

Results

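Transcript levels were measured on 12 arrays in 3 groups of L40 yeast: 4 arrays of cells expressing scFv-58F (58F below), an intrabody against histone H3 acetylated at K9, 4 of cells expressing the control intrabody scFv-112A (112A), and 4 of wild type cells. The 75th percentile of the processed signal was 4739 to 5782 on the 58F arrays, 4984 to 5254 on the 112A arrays and 5592 to 6047 on wild type replicates 2 to 4, against 9362 on wild type replicate 1. Replicates correlated across genes with r of 0.996 to 0.999 in 58F, 0.993 to 0.997 in 112A and 0.993 to 0.997 in wild type. Genes are not independent replicates, and these values describe the arrays only.

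LEU2 (YCL018W), an enzyme of leucine synthesis and the marker that medium without leucine selects for, checked the group labels first. It was 24.6-fold higher in 58F than in wild type (log2 change 4.62 ± 0.08, adjusted p = 2.44e-12) and 20.5-fold higher in 112A than in wild type (4.35 ± 0.08, adjusted p = 4.89e-12). All 8 intrabody arrays lay above all wild type arrays: the log2 level above the array's 75th percentile was 6.15 ± 0.09 in 58F, 5.88 ± 0.16 in 112A and 1.53 ± 0.07 in wild type (mean and SD, n = 4). LEU2 was also 0.26 ± 0.08 higher in 58F than in 112A (adjusted p = 0.0219), a call lost without 58F replicate 2 (adjusted p = 0.0627), without 58F replicate 3 (0.0638) and after quantile scaling (0.103). LEU1, the preceding enzyme of the pathway, went the other way and was 5.64-fold lower in 58F and 5.43-fold lower in 112A than in wild type. The label check therefore separates intrabody arrays from wild type arrays and does not by itself tell 58F from 112A.

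**Figure D1:**
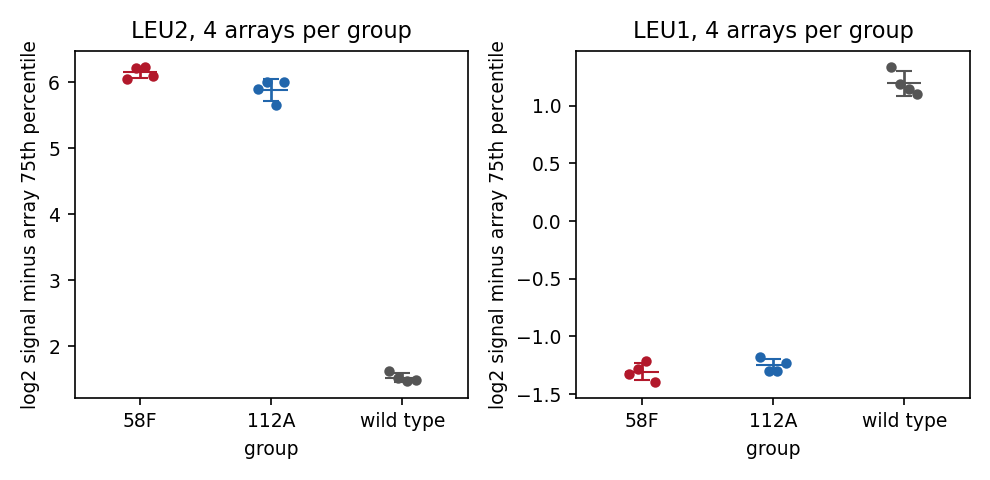
Level of LEU2 and LEU1 on each array, as log2 signal minus the array's 75th percentile, for 58F, 112A and wild type; points are arrays, long bars means and error bars the SD of 4 arrays. LEU2 lies at 1.47 to 1.62 in wild type and at 5.65 to 6.23 in the intrabody strains.

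The comparison of 58F with 112A asks what differs when the intrabody binds acetylated histone H3 instead of a target foreign to yeast. The cells expressing 58F had less transcript of the phosphate transporters PHO89 and PHO84 (4.23-fold and 3.65-fold lower), of the sulfate permease SUL1 (2.95-fold), of the respiratory cytochrome CYC1 (2.66-fold) and of the chaperone gene SSA3 (2.3-fold). They had more of ANB1, the low-oxygen form of a translation factor (2.32-fold higher, or 1.38-fold with normexp background), of the purine synthesis gene ADE17 (2.09-fold) and of the glucose transporter HXT2 (1.8-fold). As groups, genes of the respiratory chain, of sulfate assimilation and methionine synthesis, of heat shock and of the tricarboxylic acid cycle were lower in 58F. With an estimated correlation these list calls were lost (adjusted p = 0.667, 0.433, 0.158 and 0.667). The lists of glycolytic and cytosolic ribosomal protein genes were called higher with 4 of 20 and 6 of 136 members called higher, and these calls were lost as well (0.726 and 0.8). The 6 of 136 is a smaller share than the 799 of 5827 for all genes. That list call reflects small shifts (median 0.16), most of them not called. Of 5827 genes tested, 1877 were called, 799 higher and 1078 lower in 58F, with 4 higher and 28 lower by at least 2-fold. The median size of a called change was 0.29 (log2), and the 4 arrays of each group did not overlap for 34.6% of genes, against 2.86% by chance.

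Among the largest falls, PHO89 (YBR296C, sodium and phosphate cotransporter) changed by -2.08 ± 0.20 (adjusted p = 9.49e-05) and PHO84 (YML123C, high-affinity phosphate transporter) by -1.87 ± 0.35 (adjusted p = 0.00215). SUL1 (YBR294W) changed by -1.56 ± 0.20 (adjusted p = 0.000269), CYC1 (YJR048W) by -1.41 ± 0.19 (adjusted p = 0.000413), the pheromone-regulated gene PRM7 by -1.57 ± 0.27 and the uncharacterized reading frame YDL218W by -1.38 ± 0.28. The metal reductase gene FRE7 changed by -1.37 ± 0.25, the copper transporter gene CTR1 by -1.18 ± 0.18 and RKI1, of the pentose phosphate pathway, by -1.14 ± 0.11 (adjusted p = 9.15e-05). COS12 (-1.63 ± 0.25), VBA3 (-1.46 ± 0.28) and VBA5 (-1.47 ± 0.31) were also among the largest falls, but each was above background on only 2 of 4 arrays in both groups. VBA3 and VBA5 are near-identical copies that share signal, and the call of VBA5 was lost after cyclic loess scaling (adjusted p = 0.058). With normexp background the changes shrank to -0.78, -0.73 and -0.72. REX4 (-1.44 ± 0.48, above background on 1 array of 58F and 2 of 112A) was called with an adjusted p of 0.0374, and the call was lost without 112A replicate 3 (0.0838) or 4 (0.0975), without 58F replicate 1 (0.0823), 2 (0.0579), 3 (0.0668) or 4 (0.0775), after quantile (0.101) or cyclic loess scaling (0.103), and with no filter on dim probes (0.0504). With normexp it was called at -0.87.

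Among the largest rises, the uncharacterized gene YJR154W changed by 1.67 ± 0.22 (adjusted p = 0.000314, above background on 4 arrays of 58F and 3 of 112A), ANB1 (YJR047C) by 1.21 ± 0.22 (adjusted p = 0.0019, 4 and 2 arrays, and 0.46 with normexp) and YBR238C by 1.12 ± 0.20 (adjusted p = 0.00199). ADE17 (YMR120C) rose by 1.06 ± 0.12 (adjusted p = 0.000149) and ADE13, which acts in the same pathway, by 0.80 ± 0.11. KTD1 (0.97 ± 0.21) and PRM9 (0.95 ± 0.18, above background on 4 and 3 arrays, and 0.57 with normexp), membrane protein genes of the DUP240 family, NRS1 (0.85 ± 0.10) and EMA17 (0.81 ± 0.11) were also higher. The glucose transporter genes HXT2 (0.85 ± 0.15), HXT4 (0.77 ± 0.16) and HXT3 (0.73 ± 0.17) were higher, although the list of hexose transporters and glucose-repressed genes did not move: of 18 members tested, 6 were higher and 4 lower, and 7 higher and 4 lower adjusted over the list alone (median 0.08, camera adjusted p = 0.401, adjusted p = 0.745 with an estimated correlation).

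Of 33 respiratory chain and ATP synthase genes, 32 were lower in 58F than in 112A and 0 higher, and 32 and 0 when adjusted over the list alone (median -0.65, camera adjusted p = 4.37e-19, adjusted p = 0.667 with an estimated correlation). Besides CYC1, the examples are COX8 (-0.90 ± 0.09), of cytochrome c oxidase, NDE1 (-0.87 ± 0.11), an NADH dehydrogenase, and ATP5 (-0.87 ± 0.10), of the ATP synthase. Of 26 genes of the tricarboxylic acid cycle, the glyoxylate cycle and gluconeogenesis, 17 were lower and 1 higher, 19 and 1 adjusted over the list alone (median -0.42, camera adjusted p = 1.49e-05, adjusted p = 0.667 with an estimated correlation). FBP1 (-1.13 ± 0.15) and PCK1 (-0.96 ± 0.18), enzymes of gluconeogenesis, and MLS1 (-0.95 ± 0.18), of the glyoxylate cycle, had the largest changes. Of 20 genes of methionine synthesis and sulfate assimilation, 19 were lower and 0 higher, also 19 adjusted over the list alone (median -0.48, camera adjusted p = 6.47e-12, adjusted p = 0.433 with an estimated correlation). MET14 fell by 0.96 ± 0.11 and MET16 by 0.88 ± 0.08 besides SUL1. Of 23 heat shock and chaperone genes, 21 were lower and 0 higher, 22 adjusted over the list alone (median -0.38, camera adjusted p = 2.30e-12, adjusted p = 0.158 with an estimated correlation). The examples are SSA3 (-1.20 ± 0.15), BTN2 (-0.99 ± 0.10), HSP26 (-0.61 ± 0.09) and YDJ1 (-0.60 ± 0.09).

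Ribosome biogenesis genes were lower in 58F, 20 of 46 with 0 higher and 27 adjusted over the list alone (median -0.35, camera adjusted p = 9.12e-06, adjusted p = 0.69 with an estimated correlation). The RNA helicase gene DBP2 (-1.04 ± 0.19) and NSR1 (-1.03 ± 0.28) were examples. The 20 became 12 without 112A replicate 1. On leaving out each array, 112A replicate 1 and wild type replicate 1 bounded the range of 12 to 29. Proteasome and ubiquitin genes were lower in 17 of 35, 0 higher, and 19 adjusted over the list alone (median -0.15, camera adjusted p = 7.85e-06, adjusted p = 0.667 with an estimated correlation), with RPT3 (-0.42 ± 0.05) and RPN1 (-0.32 ± 0.06) as examples. Oxidative stress and thiol redox genes were lower in 13 of 24 with 1 higher, 14 and 1 adjusted over the list alone (median -0.20, camera adjusted p = 0.00054, adjusted p = 0.667 with an estimated correlation). AAD6 (-1.07 ± 0.13) and OYE3 (-0.81 ± 0.12) were the examples, and the 13 became 8 without 58F replicate 1. Leucine and branched-chain synthesis genes were lower in 5 of 12, also 5 adjusted over the list alone (median -0.26, camera adjusted p = 0.00269, adjusted p = 0.667 with an estimated correlation). ILV5 (-0.79 ± 0.11) and the mitochondrial carrier gene OAC1 (-0.55 ± 0.07) were examples. Thiamine and pyridoxine genes were lower in 10 of 22 and higher in 1, 10 and 1 when adjusted over the list alone (median -0.15, camera adjusted p = 0.00454, adjusted p = 0.667 with an estimated correlation), for example SNZ3 (-0.78 ± 0.11) and THI11 (-0.62 ± 0.08), both from families of near-identical copies. The seripauperin (PAU) genes, also near-identical, were lower in 11 of 24, 14 adjusted over the list alone (median -0.12, camera adjusted p = 0.000348, adjusted p = 0.667 with an estimated correlation). PAU17 (-0.33 ± 0.05) was the example, and the 11 became 6 without 112A replicate 1. The subtelomeric list had 88 of 300 genes lower and 26 higher, 93 and 27 adjusted over the list alone (median -0.09, camera adjusted p = 0.0046, adjusted p = 0.667 with an estimated correlation), and it includes YJR154W and PHO89. The iron regulon had 7 of 24 lower and 1 higher, also 7 and 1 adjusted over the list alone (median -0.14, camera adjusted p = 0.0232, adjusted p = 0.69 with an estimated correlation). FRE1 (-0.66 ± 0.14) was an example. Its call was lost without 112A replicate 3 (adjusted p = 0.0736), 112A replicate 4 (0.0666) or 58F replicate 3 (0.0593) and with normexp (0.0683), and the 7 became 4 without 112A replicate 1. Against wild type, 58F gave no call for PAU (median 0.03, camera adjusted p = 0.3), thiamine (0.01, 0.937) or subtelomeric genes (0.06, 0.283). Nor did it for ribosome biogenesis (-0.28, 0.213, 7 of 46 higher and 19 lower) or the iron regulon. The PAU, thiamine, subtelomeric and iron lists were called higher in 112A than in wild type, likewise only with the preset correlation.

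Higher lists were fewer. For glycolysis and fermentation 4 of 20 genes were higher and 1 lower, 8 and 1 adjusted over the list alone (median 0.24, camera adjusted p = 0.0153, adjusted p = 0.726 with an estimated correlation). TPI1 (0.46 ± 0.11) and PGI1 (0.43 ± 0.09) were higher and the pyruvate decarboxylase isozyme gene PDC6 (-0.89 ± 0.09) was lower; 10 genes were higher without 112A replicate 2. Cytosolic ribosomal protein genes shifted little each, with 6 of 136 higher and 4 lower and 1 and 1 adjusted over the list alone (median 0.16, camera adjusted p = 0.000348, adjusted p = 0.8 with an estimated correlation). RPS9A was lower (-1.04 ± 0.17). The call was lost without 112A replicate 3 (adjusted p = 0.109), and 60 genes were higher without 112A replicate 2 and 2 without 58F replicate 3. Purine genes did not move as a list: of 14 members tested, 6 were higher and 3 lower, likewise 6 higher and 3 lower adjusted over the list alone (median 0.03, camera adjusted p = 0.283, adjusted p = 0.8 with an estimated correlation). For the phosphate regulon, of 16 members tested, 1 was higher and 3 lower, and 3 higher and 4 lower adjusted over the list alone, without a call for the list (median -0.04, camera adjusted p = 0.486, adjusted p = 0.8 with an estimated correlation); SPL2 was also lower (-0.97 ± 0.14). Mating genes did not move as a list either (median -0.17, camera adjusted p = 0.382, adjusted p = 0.8 with an estimated correlation), although FAR1, an inhibitor of the cell cycle in mating, was lower (-0.70 ± 0.05). ERO1, an oxidase of the endoplasmic reticulum, was lower (-0.85 ± 0.14) in a folding list that missed the threshold (median 0.07, camera adjusted p = 0.059, adjusted p = 0.667 with an estimated correlation). The folding list was called without 112A replicate 4 (adjusted p = 0.0409), 58F replicate 3 (0.04) or 58F replicate 4 (0.0358), with no filter on dim probes (0.0426) and after quantile scaling (0.0488).

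No chromatin list other than that of the histones was called. Of 22 SAGA and H3 acetyltransferase genes 4 were higher and 4 lower, 4 and 6 adjusted over the list alone (median 0.05, camera adjusted p = 0.492, adjusted p = 0.8 with an estimated correlation). GCN5 (YGR252W), the acetyltransferase of the SAGA complex, was 0.21 ± 0.04 higher (adjusted p = 0.00165), while ADA2 (-0.26 ± 0.06), HFI1 (-0.47 ± 0.11) and ELP3 (-0.38 ± 0.10) were lower. Of 23 deacetylase and silencing genes 4 were higher and 6 lower, also 4 and 6 adjusted over the list alone (median 0.02, camera adjusted p = 0.558, adjusted p = 0.745 with an estimated correlation). RPD3 (0.23 ± 0.06, adjusted p = 0.0103) and HOS3 (0.32 ± 0.05) were higher, SIR1 was lower (-0.35 ± 0.05), and UME6 (0.55 ± 0.11, above background on 4 and 3 arrays) was called, a call lost with normexp background (log2 change 0.12, adjusted p = 0.207). For H3 methylation and chromatin remodelling, of 25 members tested, 3 were higher and 4 lower, and 3 higher and 4 lower adjusted over the list alone (median 0.00, camera adjusted p = 0.645, adjusted p = 0.845 with an estimated correlation). Core and variant histone genes were lower in 5 of 11, also 5 adjusted over the list alone (median -0.27, camera adjusted p = 0.0305, adjusted p = 0.667 with an estimated correlation), a call lost without 112A replicate 2 (adjusted p = 0.0784), 112A replicate 3 (0.108) or 58F replicate 2 (0.0557); it was also lost with normexp (0.0683) and after quantile (0.0665) or cyclic loess scaling (0.0549). Without 58F replicate 1, 3 were lower, and without 112A replicate 4, 8 were. HTB1 changed by -0.54 ± 0.10, HTA2 by -0.34 ± 0.09, HTA1 by -0.27 ± 0.07 and the H3 gene HHT1 by -0.37 ± 0.10 (adjusted p = 0.0172). The calls of HTA1 and HHT1 were lost after quantile (adjusted p = 0.146 and 0.237) and cyclic loess scaling (0.0935 and 0.0826), and that of HHT1 also without 58F replicate 1 (0.0536) or 2 (0.0514). The other H3 gene, HHT2, differed by -0.13 ± 0.07 (adjusted p = 0.158), which became a call without 112A replicate 4 (0.0314). PHO5, a phosphatase gene often used to study promoter chromatin, differed by 0.43 ± 0.16 and was not called (adjusted p = 0.0609). It was called without 112A replicate 2 (0.0153), after quantile (0.0393) or cyclic loess scaling (0.0434), and with the filter on all arrays (0.0487).

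The other lists without a call in this comparison were those of cell wall integrity, COS genes, DNA damage, ergosterol and anaerobic mannoproteins, DNA replication, mitosis, galactose use, Gcn4-regulated amino acid synthesis, meiosis, mitochondrial ribosomal proteins, multidrug resistance, NAD synthesis, nitrogen catabolite repression, trehalose and general stress, and zinc and copper. Over all 23 lists without a call the adjusted p ran from 0.059 to 0.801. Of these, cell wall genes were called without 112A replicate 1 (adjusted p = 0.0311) and after cyclic loess scaling (0.0442). Gcn4-regulated genes were called without 112A replicate 3 (0.0493) and after cyclic loess (0.0282) or quantile scaling (0.0259). COS genes were called without wild type replicate 1 (0.0381), with the filter on all arrays (0.0286), in the authors' values (0.0311), after cyclic loess (0.0227) or quantile scaling (0.0488) and in a fit of the 2 groups alone (0.036). In all, 15 lists moved, 2 up and 13 down, and with an estimated correlation 0 did (lowest adjusted p 0.158). Median and mean differ in sign for 4 lists, none of them called. Over the 24 alternatives, the fewest members called lower were 0 for the proteasome, PAU and histone lists and 4 for ribosome biogenesis. The fewest were 8 for heat shock and for the tricarboxylic acid list, 9 for methionine and 24 for the respiratory chain. Scaling on the spike-in sequences moved the median of all genes from -0.02 to -0.10 and left 210 genes called, 22 higher and 188 lower, or 1351 without wild type replicate 1, which is not part of this comparison but enters the spread of the fit. The 15 lists that moved kept the sign of their median, but the PAU list (adjusted p = 0.0751) and the iron regulon (0.0604) lost their calls. Of the lists not called, those of deacetylases (-0.06), purine (-0.05), SAGA (-0.03) and folding genes (-0.01) turned to a median below 0. Among named genes the calls of ADA2, ELP3, GCN5, HFI1, HHT1, HOS3, HTA1, HTA2, HTB1, LEU2, PAU17, PGI1, RPD3, RPN1, RPT3, SIR1, TPI1 and UME6 were lost under that scaling, although the lower ones had changes of -0.62 to -0.34 there, against -0.54 to -0.26 before, and the higher ones 0.13 to 0.47, against 0.21 to 0.55.

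Against wild type, genes of the respiratory chain, of chaperones and of leucine synthesis were lower in 58F as groups, calls that were lost with an estimated correlation (adjusted p = 0.603, 0.202 and 0.519). The comparison asks how cells with the anti-histone intrabody differ from cells with none, and it contains every effect of carrying an intrabody and its marker. Leucine synthesis genes LEU1 (5.64-fold lower) and ILV5 (4.85-fold), the gluconeogenic FBP1 (4.66-fold), the glyoxylate cycle gene MLS1 (4.49-fold), the chaperone gene SSA3 (4.5-fold) and CYC1 (3.92-fold) were lower in 58F. The pyruvate decarboxylase gene PDC5 (5.61-fold higher), ANB1 (3.83-fold) and the glucose transporter gene HXT2 (3.14-fold) were higher. In total 3594 of 5827 genes were called, 1672 higher and 1922 lower, with 51 higher and 156 lower by at least 2-fold. The median size of a called change was 0.37, and the arrays of the groups did not overlap for 57.8% of genes (2.86% by chance). Scaling on the spike-in sequences moved the median of all genes from -0.02 to -0.50, or to -0.32 without wild type replicate 1, and left 80 genes higher and 3550 lower, of which 13 and 671 by at least 2-fold. All changes below are relative to the 75th percentile of each array.

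Besides LEU2, rises were called for probes with no signal above background on any wild type array: YOL085C at least 8.41-fold, YOR050C at least 7.33-fold and SCEI, a mitochondrial endonuclease gene, at least 3.78-fold higher (the last above background on 2 of 4 arrays of 58F). These bounds hold for the processed signal only: with normexp background the fitted changes were 4.44-fold, 3.64-fold and 2.58-fold. PDC5 changed by 2.49 ± 0.12 (adjusted p = 5.73e-08), YJR154W by 2.06 ± 0.22 (adjusted p = 9.31e-06), ANB1 by 1.94 ± 0.22 (above background on 1 wild type array, and 1.06 with normexp), YBR238C by 1.84 ± 0.20, PRM9 by 1.74 ± 0.18 (2 wild type arrays) and HXT2 by 1.65 ± 0.15. Among the largest falls were LEU1 (YGL009C, -2.49 ± 0.06, adjusted p = 8.27e-11), YDL218W (-2.37 ± 0.28), PHO89 (-2.34 ± 0.20), ILV5 (-2.28 ± 0.11), PRM7 (-2.23 ± 0.27), FBP1 (-2.22 ± 0.15), BTN2 (-2.20 ± 0.10), SUL1 (-2.20 ± 0.20), SSA3 (-2.17 ± 0.15) and MLS1 (-2.17 ± 0.18). RKI1 was also lower (-2.08 ± 0.11). The hexose transporter genes HXT1 (1.39 ± 0.12), HXT13 (1.49 ± 0.15, and 0.93 with normexp) and HXT16 (1.45 ± 0.12) were higher, the last 2 near-identical, while their list was not called (median 0.17, camera adjusted p = 0.237, adjusted p = 0.631 with an estimated correlation). Under spike-in scaling that list was called higher than other genes (adjusted p = 0.000299), with a median of -0.31.

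Leucine and branched-chain synthesis genes were lower in 10 of 12 and higher in 1, 10 and 1 adjusted over the list alone (median -1.11, camera adjusted p = 4.02e-05, adjusted p = 0.519 with an estimated correlation). Besides LEU1 and ILV5 these were OAC1 (-1.66 ± 0.07) and BAT1 (-1.65 ± 0.12). On wild type replicate 1 this list lay at 0.22 against the other wild type arrays, and without it the list gave median -1.06 and adjusted p = 6.55e-05. Respiratory chain genes were lower in 32 of 33 and higher in 0, also 32 adjusted over the list alone (median -0.88, camera adjusted p = 5.50e-13, adjusted p = 0.603 with an estimated correlation). CYC1 (-1.97 ± 0.19), COX5A (-1.32 ± 0.13) and COX8 (-1.27 ± 0.09) were examples. Heat shock and chaperone genes were lower in all 23, as adjusted over the list alone (median -0.80, camera adjusted p = 2.21e-11, adjusted p = 0.202 with an estimated correlation). YDJ1 (-1.61 ± 0.09) and HSP12 (-1.32 ± 0.11) were examples. Tricarboxylic acid, glyoxylate and gluconeogenic genes were lower in 20 of 26 and higher in 1, also 20 and 1 adjusted over the list alone (median -0.59, camera adjusted p = 6.53e-06, adjusted p = 0.603 with an estimated correlation). PCK1 (-1.71 ± 0.18) was an example. Methionine and sulfate genes were lower in 18 of 20, also 18 adjusted over the list alone (median -0.52, camera adjusted p = 4.52e-07, adjusted p = 0.519 with an estimated correlation). MET16 (-1.10 ± 0.08) and MET6 (-1.05 ± 0.08) were examples. Mitochondrial ribosomal protein genes were lower in 40 of 56 and higher in 2, 42 and 2 adjusted over the list alone (median -0.29, camera adjusted p = 2.31e-06, adjusted p = 0.603 with an estimated correlation). MRPL3 (-0.92 ± 0.12) and MRPL20 (-0.77 ± 0.07) were examples. Proteasome genes were lower in 27 of 35, also 27 adjusted over the list alone (median -0.29, camera adjusted p = 1.45e-05, adjusted p = 0.603 with an estimated correlation). RPN1 (-0.60 ± 0.06) and the regulator gene RPN4 (-0.57 ± 0.07) were examples.

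Genes repressed by good nitrogen sources were lower in 19 of 26 and higher in 1, 20 and 1 adjusted over the list alone (median -0.41, camera adjusted p = 2.00e-05, adjusted p = 0.519 with an estimated correlation). GDH1 (-1.14 ± 0.11) and the permease gene AGP1 (-0.85 ± 0.09) were examples. Gcn4-regulated amino acid genes were lower in 20 of 33 and higher in 5, also 20 and 5 adjusted over the list alone (median -0.24, camera adjusted p = 0.00662, adjusted p = 0.603 with an estimated correlation). HOM3 (-1.62 ± 0.10) and ASN1 (-1.10 ± 0.06) were examples. Oxidative stress genes were lower in 17 of 24 and higher in 2, 18 and 2 adjusted over the list alone (median -0.29, camera adjusted p = 0.00255, adjusted p = 0.603 with an estimated correlation). TRX3 (-0.97 ± 0.08) and TSA2 (-0.90 ± 0.07) were examples. Histone genes were lower in 8 of 11, also 8 adjusted over the list alone (median -0.59, camera adjusted p = 0.00662, adjusted p = 0.603 with an estimated correlation): HHF1 changed by -1.11 ± 0.21, HHF2 by -1.05 ± 0.25, HTB2 by -0.90 ± 0.21, HHT1 by -0.81 ± 0.10 and HHT2 by -0.45 ± 0.07, whose call was lost after quantile scaling (adjusted p = 0.0528).

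Spike-in scaling lowers every gene against wild type by 1 amount per array, and the medians given for it below include that shift. Under it camera called the ribosomal (adjusted p = 7.92e-17), glycolysis (7.80e-07), COS (0.00193) and cell wall lists (0.00776) higher than other genes. The shift leaves the differences between the genes' fold changes as they were, so these calls add no independent support. They use the preset correlation, and an estimated one was not run under this scaling. Cytosolic ribosomal protein genes were higher in 89 of 136 and lower in 9, 94 and 11 adjusted over the list alone (median 0.45, camera adjusted p = 3.02e-07, adjusted p = 0.661 with an estimated correlation), while spike-in scaling turned the median to -0.03, with 6 higher and 22 lower. RPL21A (0.99 ± 0.18) and RPS0A (0.96 ± 0.16) were higher, RPS9A (-1.51 ± 0.17) and RPL14A (-0.98 ± 0.08) lower. On wild type replicate 1 this list lay at -0.21 against the other wild type arrays, and without it the list gave median 0.40 and adjusted p = 2.04e-05. Glycolysis and fermentation genes were higher in 15 of 20 and lower in 2, 16 and 2 adjusted over the list alone (median 0.51, camera adjusted p = 0.00255, adjusted p = 0.631 with an estimated correlation), with a median of 0.0048 under spike-in scaling (2 higher and 4 lower). ADH1 (0.95 ± 0.14) and ENO2 (0.86 ± 0.14) were higher. This list lay at -0.39 on wild type replicate 1, and without that array it gave median 0.41 and adjusted p = 0.00785. COS genes, near-identical subtelomeric copies, were higher in 9 of 12 with 0 lower, 10 adjusted over the list alone (median 0.39, camera adjusted p = 0.00136, adjusted p = 0.547 with an estimated correlation), turning to a median of -0.09, 0 higher and 0 lower under spike-in scaling, with COS6 (0.65 ± 0.04). Their median lay at -0.33 on wild type replicate 1, and without it they gave median 0.32 and adjusted p = 0.00113. Cell wall integrity genes were higher in 15 of 26 and lower in 6, also 15 and 6 adjusted over the list alone (median 0.20, camera adjusted p = 0.00662, adjusted p = 0.519 with an estimated correlation), turning to -0.28, 1 higher and 10 lower under spike-in scaling, with YPS1 (1.00 ± 0.07) and CRH1 (0.80 ± 0.07). TIR1 (1.23 ± 0.12), a mannoprotein gene of anaerobic cells, and UPC2 (1.14 ± 0.10), a regulator of sterol synthesis, were higher in a list that missed the threshold (median 0.20, camera adjusted p = 0.0566, adjusted p = 0.631 with an estimated correlation). It was called without wild type replicate 1 (adjusted p = 0.0245), 58F replicate 2 (0.0387) or 58F replicate 3 (0.03), with median scaling (0.0452) and with spike-in scaling (0.000964, median -0.28). The iron regulon was not called (median 0.19, camera adjusted p = 0.0692, adjusted p = 0.642 with an estimated correlation), but it was without 58F replicate 3 (0.0156) and under spike-in scaling (0.00663, median -0.29). In all, 15 lists moved, 4 up and 11 down, and 0 with an estimated correlation (lowest adjusted p 0.202). Median and mean differ in sign for 3 lists. Under spike-in scaling COS6 (0.17), CRH1 (0.32) and ENO2 (0.38) lost their calls.

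GCN5 was 0.49 ± 0.04 higher in 58F than in wild type (adjusted p = 9.85e-07), HDA2 0.49 ± 0.04, SDC1 0.69 ± 0.09 and CHD1 0.70 ± 0.08, with 0.01, 0.01, 0.21 and 0.22 under spike-in scaling and no call there. ADA2 (-0.75 ± 0.06), the H3 methyltransferase gene SET2 (-0.95 ± 0.08) and UME1 (-0.64 ± 0.07) were lower. RPD3 was higher by 0.20 ± 0.06 (adjusted p = 0.00765), reversed to -0.28 by spike-in scaling. For the SAGA list, of 22 members tested, 6 were higher and 6 lower (median -0.01, camera adjusted p = 0.756, adjusted p = 0.901 with an estimated correlation); for deacetylases, of 23 members tested, 8 were higher and 7 lower (median 0.04, camera adjusted p = 0.475, adjusted p = 0.631 with an estimated correlation); for H3 methylation and remodelling, of 25 members tested, 8 were higher and 7 lower (median 0.03, camera adjusted p = 0.625, adjusted p = 0.901 with an estimated correlation). Adjusted over the list alone these counts were 6 and 6, 8 and 7, and 8 and 7. Under spike-in scaling the medians of deacetylases (-0.44) and of H3 methylation (-0.45) lay below 0 with that of all genes. Of the marker genes, HIS3 was lower (-0.36 ± 0.08), as was URA3 (-0.21 ± 0.05), a call lost after quantile (adjusted p = 0.885) and cyclic loess scaling (0.819). LYS2 was higher (0.49 ± 0.07) and 0.01 under spike-in scaling, GAL4 was higher (0.37 ± 0.06) and reversed to -0.11 there, and ADE2 differed by -0.13 ± 0.08 without a call (adjusted p = 0.147), with a call under normexp (0.0299) and spike-in scaling (0.00624). TRP1 was above background on 0 arrays and was not tested. PHO5 was higher by 0.51 ± 0.16 (adjusted p = 0.0175), a call lost without 58F replicate 4 (0.0503), without wild type replicate 2 (0.0505) and under spike-in scaling (0.03, adjusted p = 0.92).

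Genes set apart in 58F, called in the same direction against 112A and against wild type, numbered 1390: 581 higher and 809 lower, with 3 higher and 17 lower by at least 2-fold in both. The lower ones with the largest changes in both comparisons were PHO89, PHO84, PRM7, SUL1, CYC1, YDL218W, FRE7, SSA3, CTR1 and RKI1, and the higher ones included YJR154W, ANB1, YBR238C, ADE17, KTD1, PRM9, HXT2 and EMA17. Independent calls would share 229.3 higher and 355.6 lower genes. Both comparisons use the 58F arrays. In 100 simulations of unchanged groups at most 1 gene was set apart, but with hardly any calls there this does not measure sharing through common arrays. When the 58F arrays were split between the comparisons in 6 ways, 724 to 905 genes were shared, with at most 121.5 higher and 205.9 lower if independent. The 58F arrays share 1 slide, so neither check removes a difference of that slide. Another 89 genes were called in opposite directions in these comparisons. Spike-in scaling left 193 genes set apart, 12 higher and 181 lower.

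**Figure D2:**
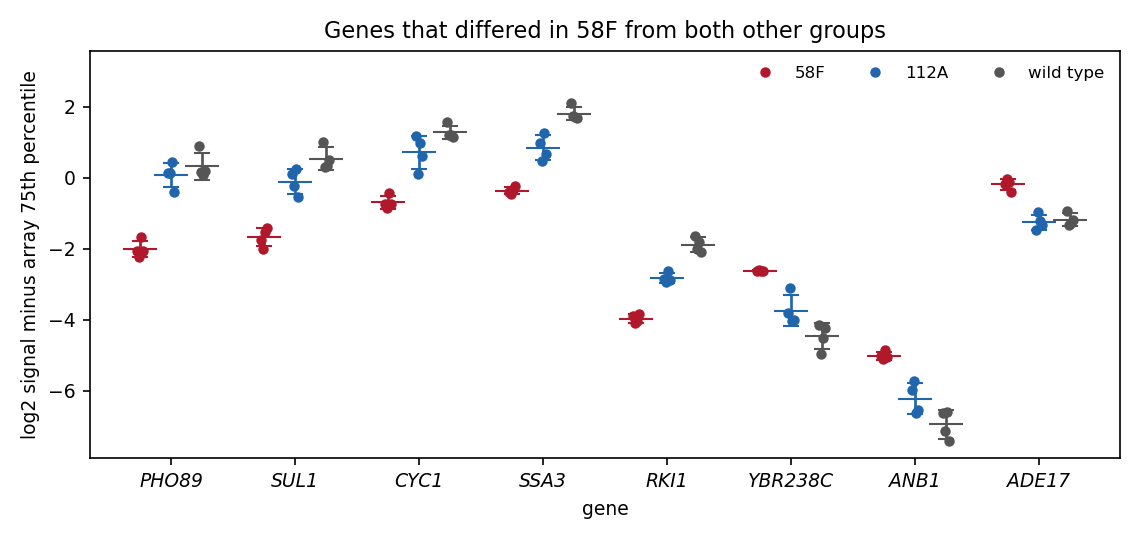
Level on each array, as log2 signal minus the array's 75th percentile, of 8 genes that differed in 58F from both 112A and wild type; points are arrays, long bars means and error bars the SD of 4 arrays. PHO89, SUL1, CYC1, SSA3 and RKI1 are lower and YBR238C, ANB1 and ADE17 higher in 58F, and the sign of the difference from 112A held under each scaling.

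Cells with the control intrabody differed from wild type in leucine metabolism, in chaperone and nitrogen genes and in iron and subtelomeric genes, list calls that were lost with an estimated correlation (adjusted p = 0.454, 0.348, 0.348, 0.592 and 0.454). The comparison asks what goes with an intrabody whose named target is not a yeast protein, and with its marker. LEU1 (5.43-fold lower), ILV5 (2.79-fold), the aldehyde dehydrogenase gene ALD5 (2.82-fold) and the aquaporin gene AQY1 (2.54-fold) were lower in 112A. PDC5 (5.6-fold higher) and the iron genes FIT3 (3.61-fold) and FRE5 (3.29-fold) were higher. In total 2817 of 5827 genes were called, 1324 higher and 1493 lower, with 24 higher and 17 lower by at least 2-fold. The median size of a called change was 0.32, and the arrays did not overlap for 39.9% of genes (2.86% by chance). Spike-in scaling moved the median of all genes from -0.01 to -0.41, or to -0.24 without wild type replicate 1, and left 54 genes higher and 2832 lower. The counts of at least 2-fold were 11 higher and 16 lower when every array had to be above background.

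Beside LEU2, YOL085C was at least 16.8-fold, YOR050C at least 8.93-fold, YGL262W at least 5.25-fold and SCEI at least 4.7-fold higher, each above background on 0 wild type arrays. YGL262W was above background on 3 of 4 arrays of 112A and SCEI on 2. With normexp background, below these bounds, the fitted changes were 7.68-fold, 4.47-fold, 2.83-fold and 3.34-fold. PDC5 changed by 2.49 ± 0.12 (adjusted p = 1.31e-07), FIT3 by 1.85 ± 0.15 (adjusted p = 5.46e-06), FRE5 by 1.72 ± 0.12, the mitochondrial intron gene AI3 by 1.57 ± 0.10 (above background on 3 wild type arrays) and COS12 by 2.26 ± 0.25 (2 arrays of 112A and 1 of wild type, and 1.35 with normexp). Among the largest falls were LEU1 (-2.44 ± 0.06, adjusted p = 1.06e-10), ALD5 (-1.49 ± 0.09), ILV5 (-1.48 ± 0.11), BAT1 (-1.39 ± 0.12), AQY1 (-1.34 ± 0.11), BTN2 (-1.22 ± 0.10), MLS1 (-1.21 ± 0.18), AGP1 (-1.18 ± 0.09) and the spore wall gene SPS100 (-1.11 ± 0.14). YGL024W (-1.46 ± 0.19), above background on 1 array of 112A, shrank to -0.39 with normexp.

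Leucine and branched-chain genes were lower in 9 of 12 and higher in 2, 10 and 2 adjusted over the list alone (median -0.79, camera adjusted p = 3.02e-05, adjusted p = 0.454 with an estimated correlation). OAC1 (-1.11 ± 0.07) was an example. Without wild type replicate 1 the list gave median -0.74 and adjusted p = 7.46e-05. Nitrogen-repressed genes were lower in 18 of 26 and higher in 1, 19 and 1 adjusted over the list alone (median -0.44, camera adjusted p = 4.78e-07, adjusted p = 0.348 with an estimated correlation). GLN1 (-0.89 ± 0.08) and GAP1 (-0.74 ± 0.08) were examples. Heat shock and chaperone genes were lower in 18 of 23, also 18 adjusted over the list alone (median -0.40, camera adjusted p = 3.93e-07, adjusted p = 0.348 with an estimated correlation). YDJ1 (-1.01 ± 0.09) and HSP12 (-0.97 ± 0.11) were examples. Mitochondrial ribosomal protein genes were lower in 38 of 56 and higher in 1, 41 and 1 adjusted over the list alone (median -0.21, camera adjusted p = 3.93e-07, adjusted p = 0.592 with an estimated correlation). MRPL20 (-0.62 ± 0.07) and MRPL8 (-0.54 ± 0.05) were examples. Respiratory chain genes were lower in 18 of 33, also 18 adjusted over the list alone (median -0.27, camera adjusted p = 0.000412, adjusted p = 0.791 with an estimated correlation), with COX5A (-0.52 ± 0.13); CYC1 (-0.56 ± 0.19, adjusted p = 0.0301) lost its call without 112A replicate 2 (-0.36, 0.0671) or 4 (0.0695), without wild type replicate 1 (0.0792) and in a fit of the 2 groups alone (0.0586). Tricarboxylic acid, glyoxylate and gluconeogenic genes were lower in 18 of 26 and higher in 2, also 18 and 2 adjusted over the list alone (median -0.33, camera adjusted p = 0.00157, adjusted p = 0.707 with an estimated correlation). FBP1 (-1.09 ± 0.15) was an example. Gcn4-regulated genes were lower in 17 of 33 and higher in 4, also 17 and 4 adjusted over the list alone (median -0.29, camera adjusted p = 0.00491, adjusted p = 0.592 with an estimated correlation). HOM3 (-0.99 ± 0.10) and ASN1 (-0.86 ± 0.06) were examples. Proteasome genes were lower in 14 of 35 and higher in 1, 13 and 1 adjusted over the list alone (median -0.07, camera adjusted p = 0.0323, adjusted p = 0.832 with an estimated correlation). RPN12 (-0.35 ± 0.05) was an example. The call of the proteasome list was lost without 112A replicate 2 (camera adjusted p = 0.0933), after quantile (0.311), cyclic loess (0.305) or spike-in scaling (0.0585), and in the authors' values (0.0741).

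All 12 lists that were higher relative to the 75th percentile were called higher than other genes under spike-in scaling as well (highest adjusted p 0.0420 with the preset correlation). Here too that scaling leaves the differences between the genes' fold changes as they were, so these calls add no independent support. The medians of these lists and counts of members under spike-in scaling are given last for each, and the medians lay below 0 with that of all genes. The iron regulon had 13 of 24 genes higher and 1 lower, also 13 and 1 adjusted over the list alone (median 0.23, camera adjusted p = 0.000212, adjusted p = 0.592 with an estimated correlation; -0.17, 3 higher and 5 lower). TIS11 (1.04 ± 0.11) and the siderophore transporter gene ARN1 (0.81 ± 0.08) were examples. The subtelomeric list had 119 of 300 higher and 42 lower, 122 and 43 adjusted over the list alone (median 0.16, camera adjusted p = 7.09e-05, adjusted p = 0.454 with an estimated correlation; -0.24, 11 higher and 84 lower), with HXT13 (1.09 ± 0.15) and YIR042C (2.46-fold, above background on 3 arrays of 112A and 2 of wild type). PAU genes were higher in 15 of 24, 16 adjusted over the list alone (median 0.16, camera adjusted p = 1.77e-05, adjusted p = 0.592 with an estimated correlation; -0.24, 0 higher and 0 lower), with PAU11 (0.51 ± 0.05), and in 9 without 112A replicate 1. COS genes were higher in 7 of 12, also 7 adjusted over the list alone (median 0.28, camera adjusted p = 0.00281, adjusted p = 0.567 with an estimated correlation; -0.12, 1 higher and 0 lower), and gave median 0.20 and adjusted p = 0.00838 without wild type replicate 1. Thiamine genes were higher in 10 of 22 and lower in 3, 11 and 3 adjusted over the list alone (median 0.19, camera adjusted p = 0.0103, adjusted p = 0.706 with an estimated correlation; -0.21, 0 higher and 4 lower). THI11 (0.71 ± 0.08) was an example. Ergosterol and mannoprotein genes were higher in 13 of 26 and lower in 5, 13 and 6 adjusted over the list alone (median 0.15, camera adjusted p = 0.0148, adjusted p = 0.627 with an estimated correlation; -0.25, 2 higher and 7 lower). TIR1 (1.38 ± 0.12), ERG6 (0.80 ± 0.08) and ERG2 (0.79 ± 0.07) were examples. Meiosis genes were higher in 12 of 28 and lower in 3, also 12 and 3 adjusted over the list alone (median 0.19, camera adjusted p = 0.00633, adjusted p = 0.518 with an estimated correlation; -0.21, 3 higher and 6 lower). SSP1 (1.13 ± 0.12), SPR3 (0.99 ± 0.18) and the inducer gene IME1 (0.89 ± 0.05) were examples. The call was lost after cyclic loess scaling (adjusted p = 0.0509).

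DNA replication genes were higher in 11 of 31 and lower in 2, also 11 and 2 adjusted over the list alone (median 0.19, camera adjusted p = 0.0329, adjusted p = 0.627 with an estimated correlation; -0.21, 1 higher and 6 lower under spike-in scaling), with POL2 (0.92 ± 0.11) and RFA3 (0.67 ± 0.09). The call was lost without 112A replicate 2 (adjusted p = 0.0678) or wild type replicate 4 (0.0572), and after quantile (0.0814) or cyclic loess scaling (0.0509). Mitosis genes were higher in 13 of 29 and lower in 4, also 13 and 4 adjusted over the list alone (median 0.15, camera adjusted p = 0.0103, adjusted p = 0.592 with an estimated correlation; -0.25, 0 higher and 6 lower). MYO1 (0.75 ± 0.07) was an example. Cell wall genes were higher in 13 of 26 and lower in 5, 14 and 5 adjusted over the list alone (median 0.22, camera adjusted p = 0.0148, adjusted p = 0.552 with an estimated correlation; -0.18, 0 higher and 7 lower). YPS1 (0.53 ± 0.07) was an example. Cytosolic ribosomal protein genes were higher in 41 of 136 and lower in 10, 33 and 8 adjusted over the list alone (median 0.29, camera adjusted p = 0.000115, adjusted p = 0.835 with an estimated correlation; -0.11, 2 higher and 17 lower), with RPL40B (0.99 ± 0.11) and RPS0B (0.88 ± 0.12), and 80 were higher without 112A replicate 3. Glycolysis genes were higher in 6 of 20 and lower in 1, also 6 and 1 adjusted over the list alone (median 0.21, camera adjusted p = 0.0336, adjusted p = 0.835 with an estimated correlation; -0.19, 2 higher and 5 lower). ADH1 (0.88 ± 0.14) and ENO2 (0.47 ± 0.14) were examples. This call was lost without wild type replicate 1 (adjusted p = 0.276), without 112A replicate 2 (0.0965) and with normexp (0.128). Ribosome biogenesis genes were not called (median 0.09, camera adjusted p = 0.158, adjusted p = 0.902 with an estimated correlation), but they were without wild type replicate 1 (0.00645) or 112A replicate 4 (0.0293), and under spike-in scaling (0.00414, median -0.31). In all, 20 lists moved, 12 up and 8 down, and 0 with an estimated correlation (lowest adjusted p 0.348). Median and mean differ in sign for 5 lists. Under spike-in scaling ARN1, ENO2, ERG2, ERG6, MYO1, PAU11, RFA3, THI11 and YPS1 lost their calls, with changes of 0.07 to 0.40.

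Histone genes were lower in 5 of 11 without a call for the list, also 5 adjusted over the list alone (median -0.32, camera adjusted p = 0.058, adjusted p = 0.707 with an estimated correlation). The list was called without 112A replicate 2 (adjusted p = 0.0371) or 3 (0.0318) and without wild type replicate 2 (0.0225), with no filter on dim probes (0.0438), with normexp (0.0246) and under spike-in scaling (0.0439). HHT1 changed by -0.44 ± 0.10 and HHT2 by -0.32 ± 0.07, both lower. ELP3 (0.74 ± 0.10), HDA2 (0.51 ± 0.04) and CHD1 (0.43 ± 0.08) were higher, with 0.34, 0.11 and 0.03 under spike-in scaling and no call there. GCN5 was higher (0.28 ± 0.04), reversed to -0.13 there, and ADA2 (-0.49 ± 0.06) and SET2 (-0.65 ± 0.08, and -0.33 with normexp) were lower. RPD3 differed by -0.02 ± 0.06 (adjusted p = 0.767, and -0.42 with adjusted p = 0.0454 under spike-in scaling) and PHO5 by 0.07 ± 0.16 (adjusted p = 0.737). HIS3 was lower (-0.39 ± 0.08), LYS2 (0.31 ± 0.07) and GAL4 (0.27 ± 0.06) were higher and reversed to -0.09 and -0.13 under spike-in scaling. ADE2 differed by -0.11 ± 0.08 (adjusted p = 0.233, called with 0.0253 under spike-in scaling) and URA3 by -0.11 ± 0.05 (adjusted p = 0.0946), which was called without wild type replicate 1 (0.0417), under normexp (0.0136) and under spike-in scaling (0.0144).

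**Figure D3:**
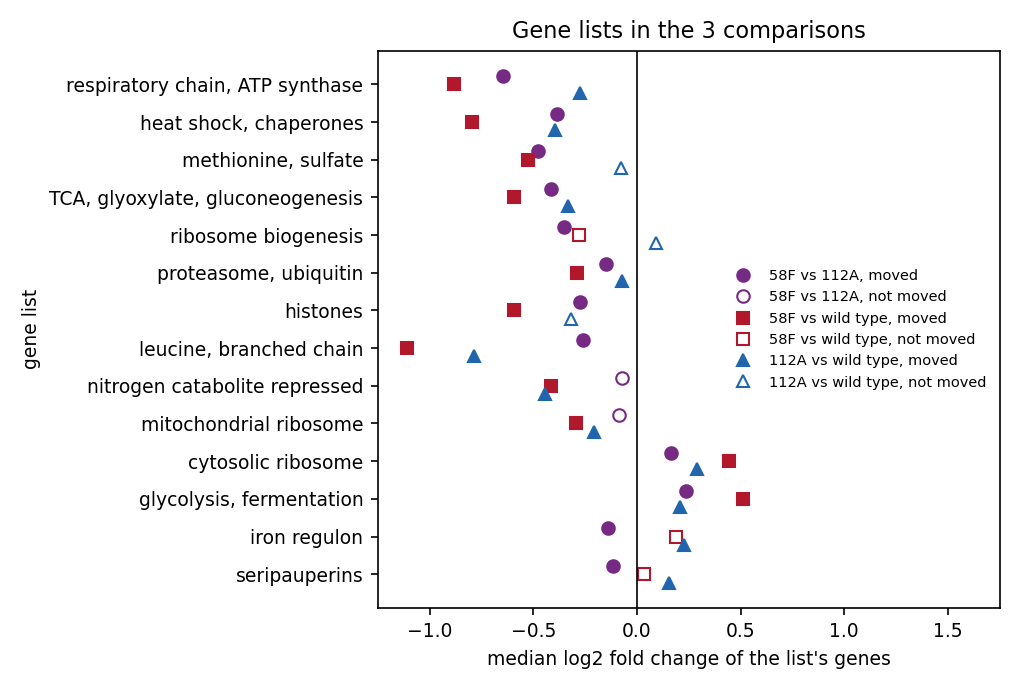
Median log2 change of 14 gene lists in the 3 comparisons; filled symbols are lists called by camera with its preset correlation, open symbols lists not called, and 0 lists were called with an estimated correlation. Respiratory chain genes lie at -0.65, -0.88 and -0.27; under spike-in scaling, with the median of all genes, the medians against wild type of cytosolic ribosomal protein, iron and PAU genes turn below 0 in both strains, and those of glycolysis and ribosome biogenesis genes in 112A.

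The changes of both intrabody strains against wild type resembled each other. LEU1, ILV5, OAC1, BAT1, BTN2, YDJ1 and MLS1 were lower, and LEU2, PDC5, TIR1, HXT13 and YPS1 were higher, in both. Of the 2817 calls of 112A, 79.3% were shared in direction with 58F, which makes 2233 genes, 1019 higher and 1214 lower, against 379.9 and 492.5 for independent calls and at most 0 in 100 simulations of unchanged groups. Unchanged groups give hardly any calls, so that simulated count was near 0 in advance. It does not measure how many real calls are shared through the common wild type arrays. Another 28 genes were called in opposite directions. Across genes the fold changes correlated with r = 0.82, against 0.51 in the simulations, where only the shared wild type arrays act. The covariance was 0.123 against 0.00603, a difference of 0.117, and 81.5% of genes had the same sign against 66.7%. With the wild type arrays split 2 and 2 in 6 ways, r was 0.70 to 0.81, the covariance 0.110 to 0.123 and the share of the same sign 75.8% to 79.8%. All wild type arrays share 1 slide and the same medium, so neither the splits nor the simulations remove a difference of that slide or medium. Genes are not independent replicates, so no p is given.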

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

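Levels here are log2 signal minus the array's 75th percentile. Each array value and each level of a gene named in the text was compared with the other 3 arrays of its group by Dixon's ratio at the 95% level. Of 441 such groups 25 held a value that stood apart, and chance gives about 22.1, so single values mean little. The tests of the patterns below were chosen after the results they measure were seen, except the splits of the arrays into other groups.

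The genes lower in 58F than in 112A include 32 of the 33 respiratory chain genes. A trend with signal intensity as the whole cause is argued against, because after cyclic loess scaling, which removes such trends, the list's median was -0.58 (quartiles -0.68 and -0.44), against -0.65 before. A lack of oxygen or haem in the 58F cultures may lower these genes: the aerobic isoform genes CYC1 (-1.41), COX5A (-0.80), PET9 (-1.04) and HYP2 (-0.33) were lower, but only 2 of 4 hypoxic isoform genes were higher, ANB1 (1.21, but 0.46 with normexp background) and COX5B (0.28, adjusted p = 0.0490), while CYC7 (0.00) and AAC3 (-0.07) were not called. The list of ergosterol and anaerobic mannoprotein genes, fixed before the data were examined, did not move between 58F and 112A. Of its 26 members tested, 2 were higher and 2 lower (median -0.02, camera adjusted p = 0.801). A rise of that list was therefore not seen, while the aerobic isoform genes were lower. These checks overlap with each other and with the pattern. CYC1 and COX5A belong to the respiratory chain list itself, so only PET9 and HYP2 add aerobic genes from outside it. ANB1 and CYC7 belong to the ergosterol and mannoprotein list. With these mixed results a lack of oxygen or haem stays open. A difference between slides also stays open and cannot be told apart from the intrabody, since 0 slides hold arrays of more than 1 group. An effect of the intrabody's target, the difference the design names, was not tested apart from these.

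Wild type replicate 1 stood apart from the other wild type arrays in its overall signal, with a median of 3079 against 1728 to 1917 and a 75th percentile of 9362 against 5592 to 6047. It also held 12 of the 23 gene levels that stood apart: ADH1 (5.41), CYC1 (1.56), ENO2 (3.53), FRE7 (0.051), HXT1 (-1.37), HXT3 (0.46), HXT4 (-0.63), OYE3 (3.43), PHO89 (0.90), PRM9 (-6.55), SNZ3 (0.27) and SSA3 (2.10). A brighter scan of the whole array is argued against, since its spike-in signal was 1.04 times that of the others while its 75th percentile was 1.62 times theirs. More labelled RNA that raised every gene by 1 factor is argued against as well. After scaling, the differences of this array from the other wild type arrays had a robust SD at least 1.503 times the largest among those (0.192 to 0.226 against 0.0997 to 0.128). Ribosome biogenesis genes lay 0.55 higher (43 of 46 above) and glycolysis genes at -0.39 (1 of 20 above). The scaling subtracts 1 amount per array, so a response that changes with signal intensity was not tested for this array. Cytosolic ribosomal protein genes lay at -0.21 on this array (12 of 136 above), opposite to the ribosome biogenesis genes. Whether a culture that differed in growth could leave this mixed pattern was not tested. The labels give no difference for this array. Across genes, its difference from the other wild type arrays correlated with the change between 58F and 112A at r = -0.34. No wild type array enters that change. Ribosome biogenesis, glycolysis and cytosolic ribosomal protein genes thus differed on 1 array without an intrabody, with signs opposite to 58F against 112A. The respiratory chain list lay at 0.04 on this array.

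Leucine pathway genes were lower in both intrabody strains than in wild type. Carry-over of amino acid limitation from the leucine-free preculture of the intrabody strains would raise, not lower, these genes through Gcn4. The leucine list argues against it for its own genes. Its quartiles were -1.66 and -0.58 in 58F and -1.18 and -0.45 in 112A, with 1 and 2 of 12 genes called higher. The test on the other Gcn4-regulated genes does not decide by itself. Their median was -0.24 in 58F (quartiles -0.73 and 0.07, 5 called higher and 20 lower) and -0.29 in 112A (-0.41 and 0.00, 4 called higher and 17 lower). A lower activity of the regulator Leu3 in cells with a working LEU2 gene may be involved: all 8 Leu3 target genes looked up, LEU1, LEU4, ILV2, ILV5, BAT1, OAC1, BAP2 and GDH1, were lower in both comparisons. Of these 8, 6 belong to the leucine list itself, and only BAP2 and GDH1 lie outside it. This is a hypothesis found and tested on the same arrays, and the difference between slides stays open here too.

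Among the 35 splits of the arrays of 2 groups into 4 and 4, only 1, the real split, gave as many calls. The real values were 1877, 3594 and 2817 for 58F with 112A, 58F with wild type and 112A with wild type. The highest other values were 1, 0 and 0. Every other split mixes the 2 groups, which widens the spread within them. Each group has its own slide, so the test cannot exclude a chance difference between slides or cultures as the source of the calls.

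The remaining levels that stood apart were, in 112A replicate 2, GLN1 (1.91), HDA2 (-1.61), MLS1 (-0.39) and RPT3 (0.87); in 112A replicate 3, BAT1 (-2.38) and PAU11 (-1.05); in 112A replicate 4, TIS11 (0.86); in 58F replicate 2, BTN2 (-2.78); in 58F replicate 3, ARN1 (-0.88) and HFI1 (-4.55); and in 58F replicate 4, GCN5 (-1.67). In both intrabody strains, 28 genes were called against wild type in opposite directions, 16 higher in 58F and lower in 112A and 12 the reverse. The difference between the strains was called for all 28. That follows from the opposite calls, since the sizes of the 2 changes add up in it, and gives no further support. Chosen after their values were seen, the largest were VBA3 (-0.69 in 58F, 0.77 in 112A), YNR064C (-0.73, 0.41), AAD4 (-0.51, 0.31), GRX8 (-0.37, 0.34), MET32 (-0.51, 0.16) and SUL2 (-0.45, 0.13).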

How the results depend on the processing

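Of the alternatives, cyclic loess scaling and the counts per list without wild type replicate 1 were chosen after seeing the data, the others before. Over 213 gene and comparison pairs named in the text, each under 24 alternatives or fewer, 4969 of 5061 values kept their sign and side of the threshold, 68 lost their call, 12 gained one and 12 changed sign; 157 pairs had no such change. Of the 12, 5 were called before and turned under spike-in scaling: GAL4 (-0.11) and RPD3 (-0.28) in 58F with wild type, and GCN5 (-0.13), LYS2 (-0.0887) and GAL4 (-0.13) in 112A with wild type. The other 7 were called neither before nor after: HHT2 in 58F with 112A under quantile scaling (0.028); RPD3 in 112A with wild type under normexp (0.0085), in the authors' values (0.0070) and on leaving out arrays (-0.056 to 0.0016); and PHO5 there under spike-in scaling (-0.33) and on leaving out arrays (-0.061 to 0.17). Spike-in scaling subtracts 1 amount per array from every gene. Under it 58F with 112A had 210 calls (22 higher, 188 lower; main 799 and 1078), 58F with wild type 80 higher and 3550 lower (1672 and 1922), of which 684 by at least 2-fold (207), 112A with wild type 54 and 2832 (1324 and 1493), of which 172 by at least 2-fold (41), and 193 genes were set apart (1390); 7 lists moved up and 11 down in 58F with wild type (4 and 11). Without wild type replicate 1 it gave 206 and 1145, 303 and 3431, and 250 and 2762. Quantile scaling gave 1073 higher and 952 lower in 58F with 112A, 8 and 20 by at least 2-fold (4 and 28), 792 and 705 set apart (581 and 809) and 4 lists up and 13 down (2 and 13). Cyclic loess gave 7 and 20 by at least 2-fold and 4 lists up and 13 down. At least 2-fold in 58F with 112A (32) fell to 15 under normexp and 19 in the authors' values; in 112A with wild type (41) it was 26 in the authors' values and 27, 11 higher and 16 lower, when all arrays had to be above background. An estimated correlation left 0, 0 and 0 lists (15, 15 and 20). The correlation of fold changes was 0.834 in the authors' values and 0.767 with no filter (0.820). The cause was not tested, except that the authors' table and the filter on all arrays hold fewer genes.

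Leaving out each array gave 1405 to 2260 calls in 58F with 112A, 3282 to 3688 in 58F with wild type and 2386 to 2882 in 112A with wild type; 29 to 43, 183 to 230 and 38 to 57 by at least 2-fold; 1052 to 1593 set apart; 13 to 16, 15 to 17 and 18 to 21 lists; and a correlation of 0.792 to 0.832. Lists that lost their call under a scaling alone were histones (normexp, quantile, cyclic loess), the iron regulon (normexp, spike-in) and PAU genes (spike-in) in 58F with 112A, and DNA replication (quantile, cyclic loess), glycolysis (normexp), meiosis (cyclic loess) and proteasome (quantile, authors' values, cyclic loess, spike-in) in 112A with wild type. The replicate number did not pair the arrays: same-number arrays correlated between -0.17 and 0.19, and 4 of 12 correlated best with their own number. A replicate block gave 1714, 3501 and 2646 calls, 32, 207 and 41 by at least 2-fold, 1300 set apart and 15, 15 and 20 lists. Signal over background limits the dimmest genes: those above background on part of a group's arrays have less certain folds.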

Other observations

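Genes in this part were chosen after their values were seen. Among features of the mitochondrial genome, 20 were tested, and 14 were higher and 1 lower than in wild type in each intrabody strain (median 0.44 in 58F and 0.48 in 112A), while 0 were higher and 1 lower in 58F than in 112A (median 0.01). Spike-in scaling put the medians against wild type at -0.04 and 0.08, and that between the strains at -0.07. SCEI was at least 3.78-fold and 4.7-fold higher (above background on 2 of 4 arrays of each strain). Others called higher in both strains included AI3 (1.22 in 58F, 1.57 in 112A), BI2 (0.99, 1.00), ATP8 (0.69, 0.82) and VAR1 (0.75, 0.60). COB, which encodes cytochrome b, was lower (-0.31, -0.17), the changes of COX1 were 0.20 and 0.02, and OLI1 was not called (0.19, 0.05). The labelling used polyadenylated RNA, per the labels, so levels of mitochondrial transcripts are uncertain.

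Neighbouring DUP240-type genes on the right arm of chromosome I, in the gene order of assembly R64, were higher in 58F than in 112A: UIP3 (0.22), KTD1 (0.97), DFP2 (0.65), PRM9 (0.95) and MST28 (0.51). Against wild type they were 0.44, 1.49, 0.59, 1.74 and 0.67 in 58F. They are related in sequence and can share signal. The medians of the 16 chromosomes ran from -0.06 to 0.03 in 58F with 112A, from -0.08 to 0.05 in 58F with wild type and from -0.05 to 0.10 in 112A with wild type, so no whole chromosome stood apart by more than 0.10.

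YOL085C was also lower in 58F, at 0.4996 times its level in 112A (adjusted p = 0.00753), and YOR050C differed by -0.29 without a call. Whether a sequence in the intrabody construct matches these probes cannot be read from the files.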
